A study of Corynebacterium glutamicum R with 6 samples.

How the data were processed

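RNA from Corynebacterium glutamicum R was measured on a custom Agilent array in 6 samples: 2 of the wild type and 2 of each of 2 sigC deletion mutants. Per the labels' protocols, total RNA was purified on columns, copied into cDNA and labelled with Cy3. The deposited spot intensities were made by the authors with Agilent Feature Extraction, version 10.5.1.1 per the file headers and 10.5.5.1 per the submitters' processing notes. The processed signal is the intensity after background subtraction and detrending, with no scaling between arrays. The authors also deposited a table of log2 values. In it, all 40264 rows had a median of exactly 0 over the 3 arrays of each experiment, and the median of each column was 0. Set against the scanner values centred in the same way, its columns had slopes between 0.981 and 1.00 and correlations between 0.986 and 0.997. The scaling before that centring is not given in the sources used here.

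The array had 45220 spots, of which 1417 were controls and were left out. The remaining 43803 spots held 40204 probes. Of the 3278 gene-level probes, 3092 had 2 spots and 186 had 3, and each tile had 1. A further 15 probes with their own ID prefix (CGRic) had 10 spots each and entered no test. Spots that the scanner software marked as outliers were left out, between 116 and 1702 per array, and 0 probe spots were saturated. The main values were log2 of the processed signal minus each array's 75th percentile, averaged over the spots of a probe. The median SD between spots of one gene-level probe on one array was 0.074. A probe was tested if it was well above background on at least 2 arrays, which left out 10 gene-level probes and 2142 tiles. A signal not well above background on every mutant array is given as a bound: the wild-type mean against the mean over mutant arrays of the higher of the probe's own signal and the lowest signal well above background.

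Groups came from the labels. Gene-level probes were tested with limma 3.58.1 in R 4.3.3, with 2 wild-type against 4 mutant arrays, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. A fit with 3 groups gave each mutant against the wild type and the difference between mutants. The design planned a fit per gene, with one probe as the fallback, and the fallback was used because no name could be assigned. None of the probe IDs matched the reference table for this species (0 of 40204; 3079 genes of another strain), so the 22 gene lists fixed before the data were examined, among them cytochrome bd oxidase, the cytochrome bc1-aa3 branch and heme a synthesis, were not analysed here.

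Named probes followed a rule fixed before the data were examined: the largest changes past the threshold, and where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p and no overlap between groups, given as values. Of these, at most 2 IDs are printed in each direction. Tiles, stretches of tiles and the group of probes at least 2-fold apart were chosen after their values were seen. A stretch needed at least 5 tiles, with gaps of at most 1 tile, each at least 2-fold apart with no overlap between the groups. Tile numbers were read as positions because the levels of neighbouring tiles correlated (r = 0.78 in the fwd set and 0.79 in the rev set, across tiles). The rev set was taken to be numbered from the other end, since fwd and rev levels correlated at -0.28 when read that way and at 0.05 by the same number.

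The replicate numbers mark the experiment: the series describes independent experiments, and the 3 arrays of an experiment share a slide. The deviations of same-numbered arrays from their group means correlated at 0.28 for the wild type with mutant 1, -0.26 for the wild type with mutant 2 and 0.37 for both mutants. A slide block is the same fit as the replicate block. Alternatives were the replicate block, quantile scaling, the array median, normexp correction with an offset of 50 on the median spot and background signals (a mean signal column was not used here), the authors' log2 table, no filter, a filter on all 6 arrays, a trended robust fit, other thresholds and each array left out. Those added after seeing the data were the genotype within each experiment, outlier-marked spots kept, and other rules for stretches.

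The fits were tested on simulated data. With 200 of 3268 gene-level probes changed, drawn from the real means and spreads, the fit of 2 wild-type against 4 mutant arrays recovered 85.1% of 2-fold, 97.0% of 4-fold and 99.7% of 16-fold changes over 20 runs. In the simulation of 34769 tiles it recovered 31.6%, 73.2% and 94.0% of changes of these sizes. All arrays were drawn independently, with the same spread in both groups and no slide effect. With 200 planted changes, the adjusted threshold is also easier to pass than with few. These shares therefore do not carry over to the real comparison, where CGR0149 was 59.1-fold lower with an adjusted p of 0.187 (limma). The rule for stretches found 6 of 6 planted ones. These were lowered 4-fold at every tile, with arrays drawn independently and no filter on dim tiles. This result therefore does not show that the rule finds weaker stretches in the real data. Figures were drawn with matplotlib.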

Results

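The data set measured RNA levels in Corynebacterium glutamicum R, a soil bacterium used for the industrial production of amino acids, in the wild type and in strains that lack sigC. The gene sigC encodes a sigma factor of the extracytoplasmic function family, a subunit that directs RNA polymerase to a set of promoters. Cells had been grown in rich medium with glucose and collected in the exponential phase. There were 6 single-colour arrays: 2 of the wild type and 2 of each of 2 independently made mutants. Each of the 2 experiments held 1 array of each strain, and the 3 arrays of an experiment shared a slide. The array carried 3278 gene-level probes, 18462 tiles of a forward set (fwd) and 18449 tiles of a reverse set (rev). Between 90.6% and 94.8% of the probe spots of an array were well above background, and the 75th percentile of the signal lay between 3729 and 5600 units. The number of arrays limits the precision of every value below. Signals are given on the log2 scale relative to each array's 75th percentile.

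The comparison of the mutants with the wild type asked which transcripts depend on sigC. The files do not pair the probe IDs with gene names, so the sigC probe could not be picked by name and the IDs are used as the files give them. The signal of 1 gene-level probe, CGR0346, fell in the mutants to a small remainder. It stood at 0.39 ± 0.31 in the wild type (SD, n = 2) and at -8.57 ± 0.69 in the mutants (SD, n = 4), which is 497-fold lower as measured. The size depends on the processing: with normexp background correction of the median spot signals and an added offset of 50, it was 64.9-fold. The unscaled signals of this probe in the mutants lay between 3.98 and 31.3 units, below that offset. The smaller fold therefore cannot be put down to the background alone. The log2 difference was -8.96 with a standard error of 0.42 and an adjusted p of 0.00082 in the limma test, and all 4 mutant arrays lay below both wild-type arrays. Of the 8 mutant spots of this probe, 5 were still well above background and 3 were not. The fall was -9.71 in experiment 1 and -8.20 in experiment 2. The 4 probes numbered next to it, 2 on each side, differed by between -0.24 and 0.25, and their smallest adjusted p was 0.999 (limma).

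CGR0346 was the only one of 3268 tested gene-level probes past the threshold in the limma test of the mutants against the wild type. At an unadjusted p under 0.05 there were 83, where 163 would arise by chance. The 1 call past the adjusted threshold became 15 without the wild type of experiment 2, of which 1 was higher in the mutants, and 3 without that of experiment 1. A fit of the genotype within each experiment, chosen after seeing the data, called 11 probes, all lower in the mutants. In this fit, and in those without a wild-type array, the spread came from the mutant arrays alone, with each wild-type array assumed to vary like them. A permutation test of 2 arrays against 4 could not go below 0.067, or 0.111 when labels are permuted within experiments.

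Tiles near the place of CGR0346 in the numbering also lost signal. CGR0346 lies at 10.6% of the probe numbering, and fwd tile 2056 and rev tile 16396 lie at 11.1% of theirs. That they share its position is inferred from their fall. These tiles were picked for their values and their place in the numbering, because the files give no coordinates. The rev tile 16396 stood at 0.78 and 0.11 in the wild type and was not well above background on any mutant array. Its fall is given as the bound of 628-fold. That bound is set by the dimmest spot well above background on each mutant array, so it depends on the background and is no firm minimum. The tile had an adjusted p of 0.064 (limma). With the replicate block, which pairs the arrays of an experiment, its adjusted p was 0.014 (limma). It was then the 1 tile past the threshold, against 0 of 34760 tiles without the block. In limma without the block, 1126 tiles had an unadjusted p under 0.05, where 1738 would arise by chance. Without the wild type of experiment 2, 80 tiles passed, 6 of them higher in the mutants, and the fit within experiments called 40, with 1 higher. The adjoining rev tile 16397 differed by -4.97 ± 0.42 (SE) and rev tile 16395 by -1.79 ± 0.23. In the fwd set, tile 2056 stood at -1.02 and -1.29 in the wild type and between -10.27 and -5.23 in the mutants. It was well above background on 1 of the 4 mutant arrays, so the size of its fall is not fixed. Higher signals lay next to the loss. The fwd tile 2059 was higher in the mutants by 3.49 ± 0.23 (SE), with an adjusted p of 0.064 in limma and 0.281 with the replicate block. Rev tile 16399 was higher by 1.86 ± 0.61 and rev tile 16400 by 1.06 ± 0.28, each with an adjusted p of 0.9996 (limma). The fwd tile 2058 differed by -0.45, the fwd tile 2057 kept a value on 1 mutant array after outlier-marked spots were left out, and the 19 fwd tiles farther out by at most 0.39. Of the other rev tiles, 16394 differed most, by -0.78, and was well above background on 1 mutant array. Rev tile 16388 came next, at -0.61.

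**Figure D1:**
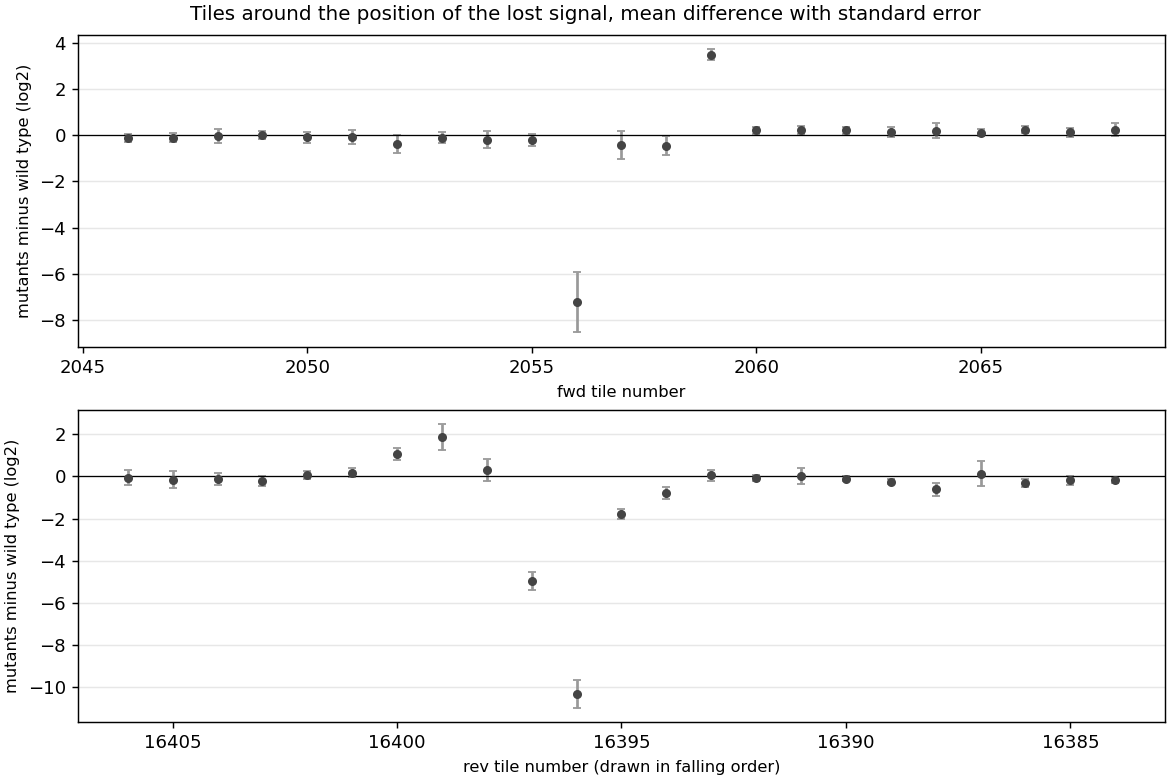
Difference between the mutants (n = 4, fewer at tiles with outlier-marked spots) and the wild type (n = 2) on the log2 scale, vertical axis, for each fwd tile (upper panel) and rev tile (lower panel) by tile number, with standard errors as bars. The fwd tile 2056 and the rev tile 16396 lay lowest, at measured values that depend on the background in the mutants, and the fwd tile 2059 lay at 3.49.

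Away from this position, 5 stretches of consecutive tiles gave lower signals in the mutants, with every mutant array below both wild-type arrays and a mean difference of at least 2-fold at each tile counted. None gave higher signals by this rule, which was chosen after seeing the data. The stretches were fwd tiles 873 to 880, fwd tiles 884 to 891, fwd tiles 13615 to 13628, rev tiles 8403 to 8411 and rev tiles 10942 to 10978. Their median signals were 24.0-fold, 2.01-fold, 12.2-fold, 2.94-fold and 6.24-fold lower in the mutants, in the same order. Together they held 73 tiles, none of which passed the threshold by itself in the limma test of 2 wild-type against 4 mutant arrays. The fit within experiments called most tiles of fwd 873 to 880, fwd 13615 to 13628 and rev 10942 to 10978. It called no tile of the other stretches. Its spread came from the mutant arrays alone, so variation between wild-type cultures did not enter these calls. Without the wild type of experiment 1, the rule gave 3 lower stretches and 1 higher, without that of experiment 2 it gave 7 lower and 4 higher, and without the experiment-1 array of mutant 1 it gave 5 lower and 2 higher. Fwd tiles 884 to 891 no longer met the rule with quantile scaling, the array median or the authors' table, which each left 4 stretches. They also failed it without the wild type of experiment 1, without either array of mutant 1 and without the experiment-2 array of mutant 2. Rev tiles 8403 to 8411 failed it without the wild type of experiment 1.

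The 4 mutant arrays gave nearly the same values in these stretches. At rev tiles 10942 to 10978, the longest stretch, the mutants stood at -2.35 ± 0.11 (SD, n = 4), and at fwd tiles 873 to 880 at -4.41 ± 0.15. The wild-type arrays differed more from each other. At rev tiles 10942 to 10978 the wild type gave 1.58 in experiment 1 and -1.003 in experiment 2, and at fwd tiles 873 to 880 it gave 1.53 and -1.18. The difference between mutants and wild type was larger in experiment 1 than in experiment 2. A limma test of that difference on single tiles, in the fit within experiments, called 0 of 34109 (smallest adjusted p = 0.480), with 2053 at an unadjusted p under 0.05. By chance 1705 would fall under 0.05 in that test, and its spread came from the mutant arrays alone. Rev tiles 10942 to 10978 were 14.6-fold lower in experiment 1 and 2.67-fold lower in experiment 2. Fwd tiles 873 to 880 were 56.9-fold and 10.1-fold lower, and fwd tiles 13615 to 13628 were 29.0-fold and 5.13-fold lower. In the other stretches the value in experiment 2 was small: 1.24-fold at fwd tiles 884 to 891 and 1.37-fold at rev tiles 8403 to 8411.

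**Figure D2:**
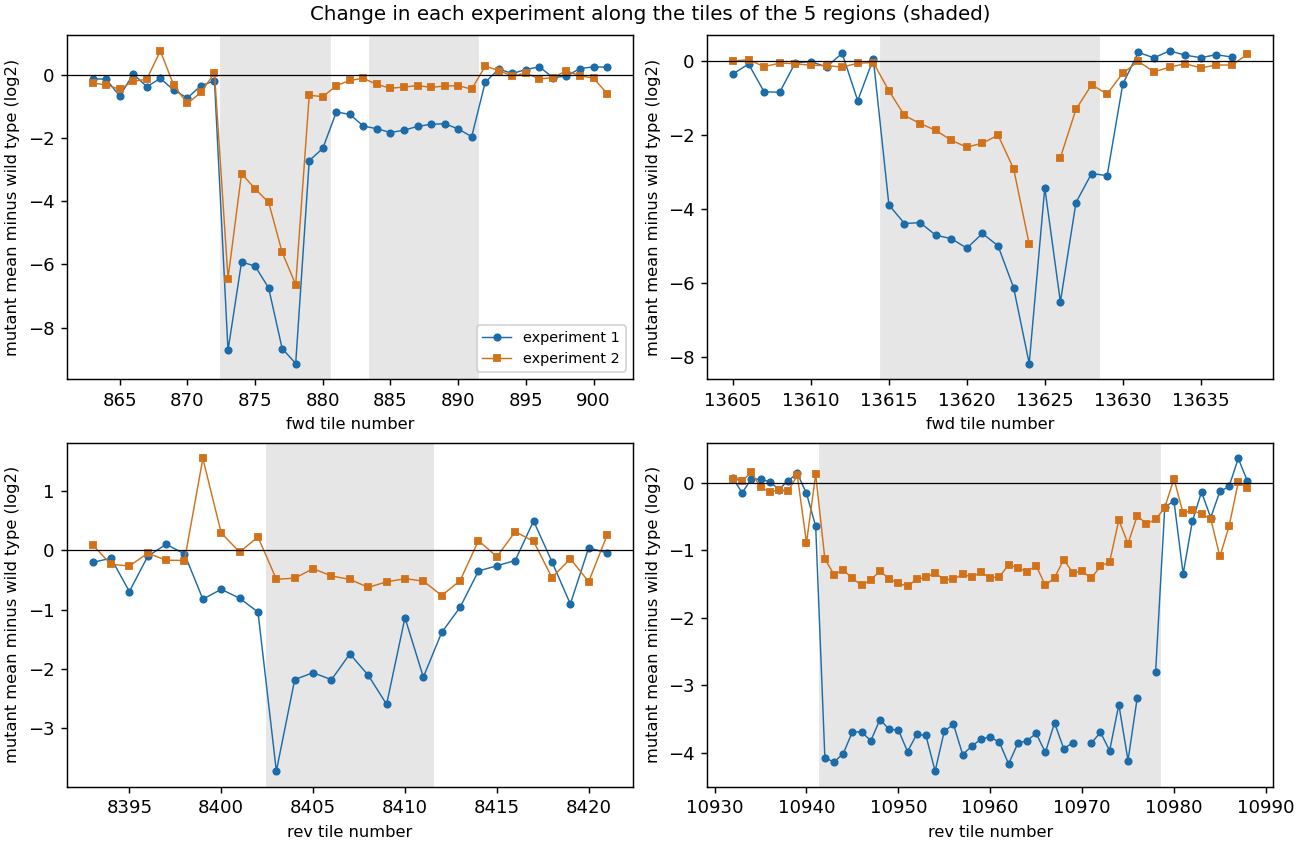
Mean of the 2 mutant arrays minus the wild-type array of the same experiment on the log2 scale, vertical axis, along the tile numbers of the 5 stretches (shaded) and 10 tiles on either side. At rev tiles 10942 to 10978, the mean of the mutant arrays' medians minus the wild-type array's median was -3.87 in experiment 1 and -1.42 in experiment 2.

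Besides CGR0346, 11 probes were at least 2-fold lower in the mutants with no overlap between the groups, and 1 was at least 2-fold higher. The calls of the fit within experiments were a different set, which held CGR0346, CGR0149 and the run of 4 named below. The spread in that fit came from the mutant arrays alone. Some of the 11 may share a locus with the stretches above. The run of 4 named below lies at 40.5% of the probe numbering, and rev tiles 10942 to 10978 start at 40.5% of theirs. CGR0149 lies at 4.55%, and fwd tile 873 at 4.73%. The choice of probes with no overlap fixed that all 11 were lower in both experiments. In experiment 2, 5 of them were less than 2-fold lower. One of the 11 lay near background, and its difference was -0.03 with normexp and its offset, against -1.01 without them. CGR0149 had the largest difference of these, at -7.35 in experiment 1 and -4.42 in experiment 2 on the log2 scale. Its mean difference was -5.88 ± 0.73 (SE), with an adjusted p of 0.187 in limma. It stood at -5.71 ± 0.11 in the mutants (SD, n = 4) and at 0.18 ± 2.14 in the wild type (SD, n = 2). A run of 4 consecutively numbered probes differed by between -2.68 and -2.56, with standard errors of up to 0.69 and an adjusted p of 0.999 each (limma). These values rest on the wild-type arrays: they lay between -3.99 and -3.74 in experiment 1 and between -1.46 and -1.37 in experiment 2. Without the wild type of experiment 2 they lay between -4.11 and -3.87, and without that of experiment 1 between -1.44 and -1.20. The values at CGR0149 were -7.40 and -4.37 in these fits. Each of them holds 1 wild-type array and takes its spread from the mutant arrays, so variation between wild-type cultures does not enter. No gene-level probe was significantly higher with all 6 arrays, and 1 was without the wild type of experiment 2. CGR0159 and CGR0160 had the smallest unadjusted p among those higher in the mutants with no overlap between the groups, with log2 differences of 0.65 ± 0.14 (SE) and 0.68 ± 0.14 (SE) and adjusted p of 0.999 for both in limma. Of all tested probes, 8.75% showed no overlap between the groups, below the 13.3% that a random order of 6 arrays gives. A random order takes no account of the shared slides, so the lower share does not measure a lack of genotype effects.

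**Figure D3:**
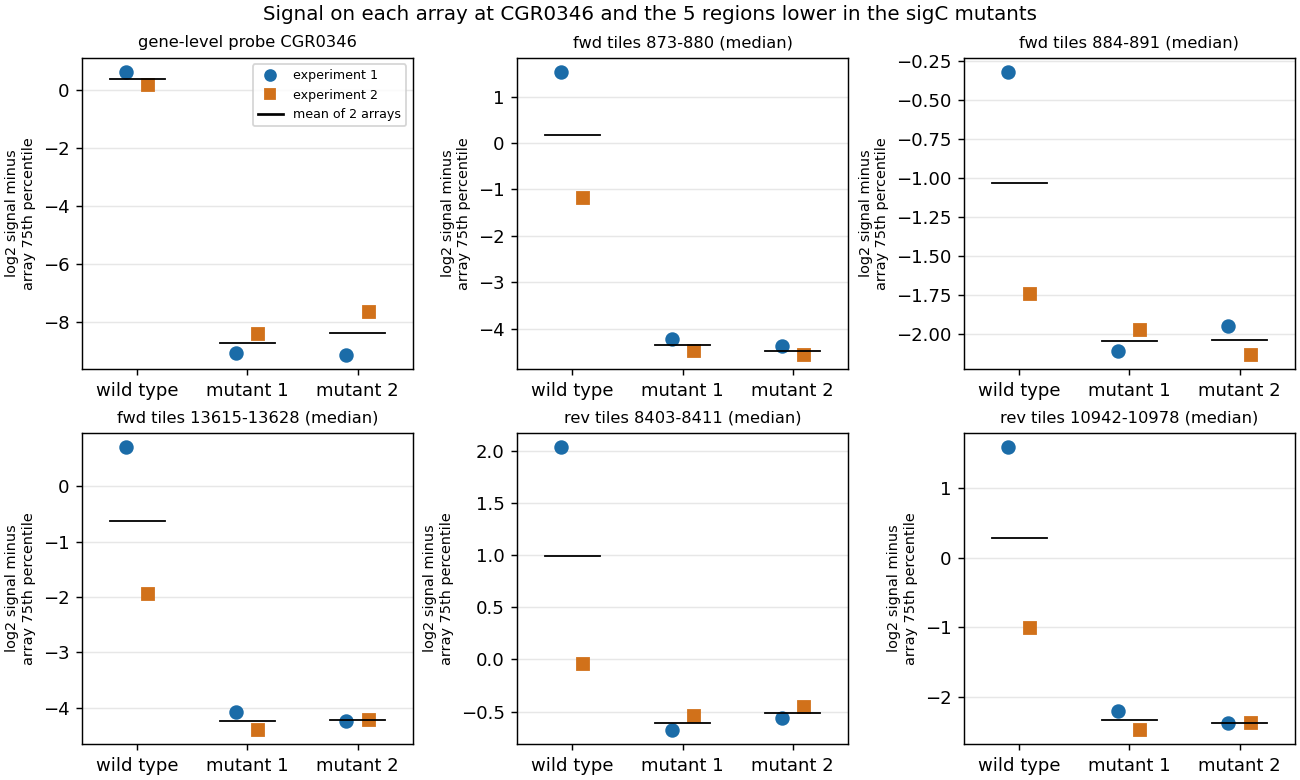
Signal on each array, log2 relative to the array's 75th percentile (vertical axis), for the gene-level probe CGR0346 and for the median of each stretch of tiles, by strain. Points are single arrays of experiment 1 (circles) and experiment 2 (squares), and lines are means of 2 arrays. CGR0346 gave 0.60 and 0.17 in the wild type, while rev tiles 10942 to 10978 gave 1.58 and -1.003.

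Each mutant was also set against the wild type on its own, to learn whether both independent deletions gave the same change. CGR0346 was the only call in mutant 1, with a log2 difference of -9.13 (adjusted p = 0.011, limma), and in mutant 2, with -8.78 (adjusted p = 0.014, limma). The call in mutant 2 was lost with the replicate block, which left 0 calls there. Without the wild type of experiment 2, each mutant had 11 calls. Without the experiment-1 array of mutant 2, that mutant had 2 calls, from 1 array assumed to vary like the other groups.

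The mutants were then compared with each other. No probe differed between them in limma (0 of 3268 at the threshold, 38 at an unadjusted p under 0.05), and 1 did without the experiment-1 array of mutant 2, which leaves that mutant 1 array assumed to vary like the other groups. By chance 163 would fall under 0.05 in this limma test, so it could miss differences between the mutants. The median absolute difference was 0.07 on the log2 scale, and 8 probes were at least 2-fold apart. Among the 11 lower probes named as a group above, the mutants differed by at most 0.23. At CGR0149 the difference between them was 0.17 ± 0.91 (SE). This standard error comes from a spread shared with the wild type, whose SD was 2.14 there, against 0.11 over the mutant arrays. It therefore does not measure the uncertainty between the mutants alone.

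The log2 changes of mutant 1 and mutant 2 correlated across gene-level probes with r = 0.83, where unchanged groups against the same wild-type arrays gave 0.49 in 20 simulations with independent arrays. With the arrays of an experiment drawn as correlated as they were measured to be, a simulation added after seeing the data, the no-change value was 0.70. The covariance was 0.071, against 0.030 and 0.039 in these simulations. Without the 13 probes that were at least 2-fold apart with no overlap between the groups, r was 0.58 and the covariance 0.019. These probes were picked for their values on the same arrays. No simulated value without them is given, so the no-change values above are not a like baseline. Genes are not independent replicates, and part of the correlation between the mutants comes from the shared wild type and the shared experiments. With a separate wild type for each mutant, r was 0.10 for mutant 1 in experiment 1 with mutant 2 in experiment 2, and 0.32 for the reverse pairing. Without the 13 probes, these values were -0.38 and -0.01. Both mutants shared their 1 call. Independent lists would share 0.00031, a number that leaves out the shared wild-type arrays, and part of the overlap may come from these.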

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

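The tests of explanations in this part were chosen after the results were seen. The effect of the genotype differed between the experiments at 8 gene-level probes in a test of that difference (limma, genotype within each experiment), and all 8 were lower by more in experiment 1. The difference was -2.93 at CGR0149 (adjusted p = 0.018). At the probe numbered after it the difference was -2.55, and at 5 probes that lie close together in the numbering it was -3.30, -2.63, -2.46, -2.38 and -2.39. At the last, which stands alone, it was -2.84. Each experiment had 1 wild-type array and the spread came from the mutant arrays only, so this test takes no account of variation between wild-type cultures, and its calls restate the gap between the wild-type arrays.

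Over the 11 lower probes other than CGR0346, the wild type of experiment 1 exceeded that of experiment 2 by a median of 2.61, against -0.04 over all tested probes. A slide effect shared by these probes would have moved the mutant arrays too, and their median difference between experiments was 0.097, at most 0.40 at any of the 11. Mutant RNA mixed into the wild-type sample of experiment 2 would have needed a share of 90.1% (median over these probes). For 10 of the 11 this was a larger share than any of 4 probes taken to lie at CGR0346 allowed (median 28.3%, at most 37.0%). A candidate explanation is that the wild-type cultures differed in the activity that the mutants lack: 10 of the 11 probes were at least 2-fold apart between the wild-type arrays and 0 between the arrays of either mutant. With 1 wild-type array per experiment, this cannot be told apart from an error in a single wild-type sample. The 11 probes were chosen for no overlap between the groups. Over all tested probes the counts ran the other way: 38 were at least 2-fold apart between the wild-type arrays, 66 between those of mutant 1 and 81 between those of mutant 2.

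The lost signal at CGR0346 may mark a DNA segment removed in the mutants. Signal was lost on both tile sets at the matching position, with a background-dependent bound of 628-fold at rev tile 16396. These tiles were picked for their fall, however. Tiles beside them were higher in the mutants, by up to 3.49 at fwd tile 2059, which the removal of a segment does not by itself predict, so the explanation stays open. Spots marked as outliers by the scanner software are no source of it, since 0 spots of CGR0346 were marked. That this probe stands for sigC is a hypothesis that the probe IDs leave open.

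At 2 of 24 items tested, a mutant array stood apart from the other 3, a different array each time, where chance gives about 1 in 20. The gap to the nearest array was 0.993 of the whole range, or 0.454 on the log2 scale, at one gene-level probe and 0.923, or 0.089, at another, both among the lower probes. The 15 probes with the CGRic prefix, which entered no comparison, were all well above background on all 6 arrays, and their log2 differences between mutants and wild type lay between -0.19 and 0.20.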

How the results depend on the processing

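The fit within experiments, the tile results, spots kept and the rules for stretches were chosen after the data were seen. The call of CGR0346 held under all 16 alternatives, with log2 changes from -9.26 to -6.02 and adjusted p from 8.8e-08 to 0.015. Of 303 single-probe values under alternatives, 281 stayed on their side of the threshold, 22 passed it newly and 0 changed sign. CGR0346 gave 16 of the 281. The others stayed short of the threshold in both settings, which does not show that their sizes held. The replicate block kept the 1 call of mutants against wild type, left 0 in mutant 2 and gave 1 tile. It changed no other call. The genotype within each experiment gave 11 gene-level probes, all lower, and 40 tiles, 1 of them higher. Tiles past the threshold, 0 in the main setting, numbered 2 with the array median, 3 with normexp, 2 in the authors' table and 2 in the trended robust fit, with 1 higher in the mutants in each. The cause was not tested. Stretches numbered 4 with quantile scaling, the array median and the authors' table, and 8 with at least 3 tiles, as the shorter minimum allows. With each array left out in turn, gene-level calls ranged from 1 to 15 in the mutants together, from 1 to 11 in mutant 1, from 1 to 11 in mutant 2 and from 0 to 1 between mutants. Stretches ranged from 3 to 7 lower, with up to 4 higher, and tiles from 0 to 80. The correlation of the mutants ranged from 0.65 to 0.91. The highest of these counts came without the wild type of experiment 2, except that between mutants, which came without the experiment-1 array of mutant 2. Leaving out an array left its strain 1 array, assumed to vary like the others. Taking the mean or the brightest of several probes, leaving out saturated spots and the gene lists were not run, since each gene number had 1 probe, no spot was saturated and no symbol matched. At low signals the fold depends on the processing: one of the 11 lower probes had a log2 change of -0.03 with normexp against -1.01. The normexp setting also adds an offset of 50, and the part of the offset was not tested apart from that of the background.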

Other observations

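The tests here were chosen after the data were seen. With a lower limit of 0.5 on the log2 scale, 7 stretches were lower in the mutants and 2 were higher. Fwd tiles 873 to 880 and fwd tiles 884 to 891 merged into 1 of the 7. The higher ones were fwd tiles 966 to 974, at a median of 0.74, and rev tiles 17514 to 17523, at 0.70. They lay at 5.23% and 5.02% of the numbering, close to fwd tiles 873 to 880 at 4.73%. Their changes were 1.15 and 1.01 in experiment 1 and 0.35 and 0.42 in experiment 2. One of the lower ones, rev tiles 737 to 744, changed more in experiment 2, by -1.68, than in experiment 1, by -0.51.

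On the opposite tile set, at the positions of the 5 lower stretches, the median change lay between -0.28 and 0.28.

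The mutant arrays of experiment 2 formed a structure of their own. Of the 15 splits of the 6 arrays into 2 and 4, the real one gave 5 stretches, and the split of these 2 arrays against the rest gave 18, of which 14 were higher in them and 4 lower. The next highest split gave 2. For gene-level probes at least 2-fold apart with no overlap, the real split gave 13, that split gave 36 and the next gave 11. That split takes both arrays from one slide, so the slide is part of its contrast. Among the 9 splits with 1 array from each experiment, the real one gave 5 stretches and 13 probes, and the other 8 gave 0 stretches and at most 10 probes. There are too few splits for a share under 0.05.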
